A study of Homo sapiens with 6 samples.

How the data were processed

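Stranded RNA-seq libraries were made from total RNA of MiaPaCa-2 cells carrying a scramble hairpin or a hairpin against GPX1, per the labels' protocols, with 3 libraries per group. The authors deposited a gene table and a transcript table whose values are FPKM, per the file headers, that is fragment counts scaled to feature length and to the mapped fragments of the library. Reads were aligned with HISAT2 to hg19, per the submitters' processing notes. The tool that computed FPKM, its annotation release and any filter on rows are not given in the sources used here. Of the deposited FPKM columns, 0 belonged to no sample.

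There were 11952 rows of genes and 29506 rows of transcripts, of which 11 and 20 name the second copy of a pseudoautosomal gene and were left out. Symbols came from a table of gene identifiers for 11865 gene rows and 29298 transcript rows. No genome annotation of the authors' build was used here, so no coordinates are given. The FPKM of a gene was not the sum over its transcripts: the median ratio of summed transcript FPKM to gene FPKM was 1.44. Among gene rows, 41 were at 0 in all libraries, and 43 genes were listed at 0 in 1 library and at 10 FPKM or more in another of the same group.

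Read counts were not used here, and low FPKM values showed no steps from which whole reads could be recovered. The depth is therefore unknown, and no counting interval or floor is given. Median gene FPKM was 4.77 to 4.85 in scramble libraries and 4.63 to 4.65 in GPx1-shRNA libraries. The top 10 genes held 4.50% to 4.79% of summed FPKM in scramble libraries and 6.01% to 6.34% in GPx1-shRNA libraries.

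Groups were taken from the labels. Values were transformed to log2(FPKM + 1), and genes or transcripts with a mean of at least 0.5 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, no covariate and a two-sided test. Adjusted p-values are Benjamini-Hochberg over the rows of a table, with a threshold of 0.05, and log2 fold changes are on the log2(FPKM + 1) scale. Errors beside FPKM are SD over 3 libraries. Before the data were examined, 33 gene lists were fixed. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists. With an estimated correlation camera uses only the residual degrees of freedom of the fit, few with 6 libraries and fewer with 1 left out. Its p can then be much larger even where the estimated correlation is below 0.01. Fry, unlike camera, does not compare a list with the other genes. Older gene symbols in the lists were matched through tables of synonyms. The second of these tables was added after a first pass over the values had matched no histone gene, and it also completed some other lists.

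The genes named were set by a rule written before the data were examined. It takes GPX1, the 12 largest rises and 12 largest falls past the threshold with a mean of at least 1 FPKM in either group and no overlap between groups, up to 4 members with the smallest p from each list, every measured GPX1 transcript, and the 5 largest rises and 5 largest falls among transcripts. Genes named otherwise are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

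The procedure was tested on simulated data with 200 changed rows. These were drawn from rows with a scramble mean of log2(FPKM + 1) above 2, so recovery at lower values was not measured. Far fewer rows were changed than were called in the real gene table. At the gene level, 46.3%, 73.1% and 86.4% of simulated log2 changes of 0.5, 1 and 2 were recovered, with 10 calls among unchanged rows of 147 calls. At the transcript level, 4.48%, 35.8% and 69.7% were recovered, with 9 such calls of 82. Of 20 simulated lists the 1 shifted list was called and 0 others with a preset correlation. The simulated rows were independent, and in the real libraries the other 9 splits of the 6 samples gave 2 to 11 list calls with that setting. Those splits still hold part of the difference between the labels, so their calls need not be false.

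The alternatives were a pseudocount of 0.1 FPKM, no filter, a filter on a mean of 2 FPKM, factors from the trimmed mean of M values, quantile normalization, the replicate letter as a block, no mean-variance trend, sample quality weights, each library left out, and a 2-fold minimum. Rows with no library at 0, list counts without scramble-shRNA replicate E, an estimated correlation in the other splits and under the other settings, and other settings for genes with transcripts called in both directions were added after seeing the data. A count test was not run, since whole reads could not be recovered.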

Results

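Total RNA was sequenced from cells labelled MiaPaCa-2, an established line from a human pancreatic carcinoma. Of the 6 libraries, 3 are labelled scramble-shRNA, a control hairpin, and 3 are labelled GPx1-shRNA, a short hairpin RNA against GPX1. This gene encodes glutathione peroxidase 1, a selenoprotein that reduces hydrogen peroxide. The comparison addresses which transcripts differ between cells carrying the hairpin against GPX1 and cells carrying the control. The replicates carry the letters D, E and F in both groups. Expression was given as FPKM for 11952 genes and 29506 transcripts. Summed gene FPKM lay between 163648 and 169982 per library, and the number of reads behind these values is unknown. Across tested genes, which are not independent replicates, Pearson's r was 0.946 to 0.955 within groups and 0.917 to 0.924 between groups. The first principal component, with 41.7% of the variance, placed the scramble libraries between -26.3 and -24.5 and the GPx1-shRNA libraries between 24.7 and 26.3. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

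The targeted gene did not separate the groups. GPX1 (ENSG00000233276.3_1) stood at 13.7, 1.21 and 80.6 FPKM in scramble-shRNA replicates D, E and F. In the libraries labelled GPx1-shRNA it stood at 7.76, 47.0 and 44.5 FPKM. The log2 difference, GPx1-shRNA minus scramble-shRNA, was 0.95 (SE 1.46, limma adjusted p = 0.674, n = 3 against 3), so the means were indistinguishable within the replicate error. Without scramble-shRNA replicate E the difference was -0.38. Among the 2 listed GPX1 transcripts, ENST00000620890.1_1 was listed at 0 in scramble replicates D and E and in GPx1-shRNA replicate D, and at 27.9, 37.1 and 35.04 FPKM in scramble replicate F and GPx1-shRNA replicates E and F. The transcript ENST00000419783.1_1 ranged from 0.713 to 78.3 FPKM within the scramble group. The neighbouring gene RHOA, chosen after its values were seen, was at 165 ± 6.81 FPKM in scramble and 148 ± 6.03 in GPx1-shRNA libraries (SD, n = 3 each; adjusted p = 0.0803). Because GPX1 RNA does not check the labels, every direction below is that of the libraries labelled GPx1-shRNA relative to those labelled scramble-shRNA.

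**Figure D1:**
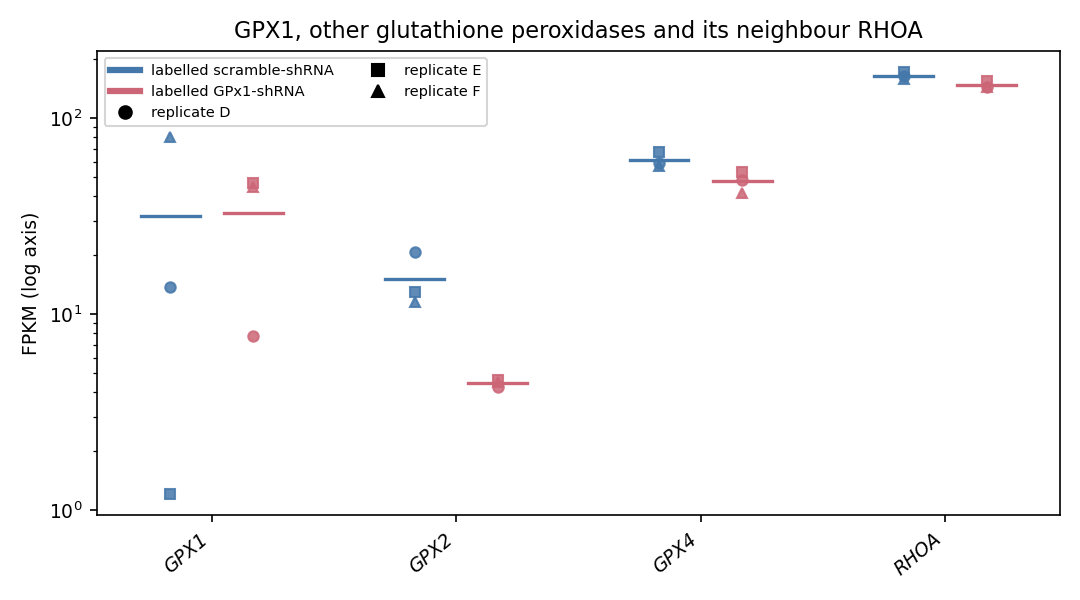
FPKM of GPX1, GPX2, GPX4 and RHOA on a log axis in each library, with a symbol for each replicate letter, colours for the labelled groups and short lines at the group means. GPX1 spans 1.21 to 80.6 FPKM within the scramble group, while RHOA stays between 144 and 173 FPKM over the 6 libraries.

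Among genes past the adjusted p threshold, the largest rises included VIM, TAGLN and MMP1, and the largest falls included LY6D, KRT13 and AQP3. VIM, which encodes the intermediate filament vimentin, rose from 25.1 ± 8.12 to 110 ± 7.85 FPKM (SD, n = 3 each). TAGLN, an actin-binding protein, rose from 6.58 ± 1.90 to 44.0 ± 13.01. The interstitial collagenase MMP1 rose from 1.33 ± 0.242 to 16.1 ± 3.78. LY6D fell from 193 ± 12.1 to 19.7 ± 1.36 FPKM. The keratin KRT13 fell from 14.4 ± 2.59 to 1.21 ± 0.255 and the water channel AQP3 from 70.3 ± 30.4 to 11.7 ± 0.701.

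The other large rises were in SRGN, which encodes the proteoglycan serglycin (0.469 ± 0.183 to 12.1 ± 0.411 FPKM), the pentraxin PTX3 (13.6 ± 1.47 to 61.0 ± 1.43), the scaffold protein AKAP12 (2.07 ± 0.198 to 12.8 ± 1.04) and ANTXR2 (3.51 ± 0.802 to 19.8 ± 0.999). ARL6IP5 rose from 3.31 ± 0.566 to 30.6 ± 17.3 FPKM. Its adjusted p was 0.0189. With 1 library left out the call held without GPx1-shRNA replicate F, and without each of the other 5 the adjusted p lay between 0.0515 and 0.061. CDCA4 had the largest fall among genes past the adjusted p threshold, from 37.9 ± 2.77 to 2.21 ± 0.409 FPKM, a log2 difference of -3.60 (SE 0.12). The kallikrein KLK6 (46.6 ± 14.3 to 4.81 ± 0.450), the elongation factor EEF1A2 (256 ± 10.5 to 35.3 ± 3.22), the retinoic acid-binding protein CRABP2 (196 ± 47.9 to 43.2 ± 13.2), the cytochrome CYP2S1 (9.15 ± 0.413 to 1.29 ± 0.122) and TRIM29 (10.5 ± 0.560 to 1.597 ± 0.0746) also fell. UPK3BL1, which has near-identical copies and is therefore uncertain, fell from 22.9 ± 2.67 to 4.37 ± 1.596.

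MT-ND2 and KBTBD7 headed the rises past the threshold by size, but each rests on values listed at 0. MT-ND2, a mitochondrially encoded subunit of complex I, was listed at 0, 0.00816 and 0 FPKM in scramble replicates D, E and F and at 1465, 1554 and 1533 in the GPx1-shRNA replicates. MT-ND5, from the same genome, was at 1641 ± 40.6 and 1633 ± 38.0 FPKM in scramble and GPx1-shRNA libraries. MT-CYB, which respiring cells use, was listed at 0 in all 6 libraries, so an exact 0 here can be a failed estimate. KBTBD7 was listed at 0 in the 3 scramble libraries and at 8.98, 9.45 and 9.70 in the GPx1-shRNA libraries.

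Among 11041 genes tested, 1113 were higher and 1796 lower in the libraries labelled GPx1-shRNA (limma, Benjamini-Hochberg adjusted p under 0.05). The 2 groups did not overlap for 46.6% of the genes tested, where chance gives 10%. Of the calls, 127 rises and 206 falls were at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. With factors from the trimmed mean of M values 1333 genes were higher and 1445 lower, so the excess of falls depended largely on scaling.

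**Figure D2:**
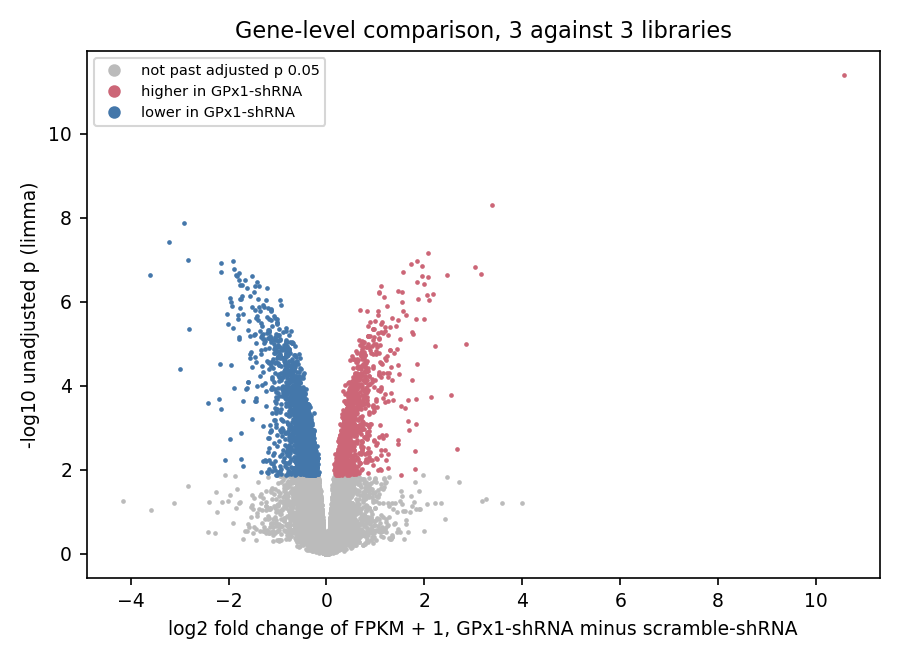
Log2 fold change of FPKM + 1 (GPx1-shRNA minus scramble-shRNA) against -log10 of the unadjusted limma p for 11041 genes, each point a gene. The coloured points are the 1113 genes higher and 1796 genes lower at an adjusted p under 0.05.

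Genes for integrins and cell-matrix adhesion rose as a group. Of 34 measured members 25 rose and 0 fell, and 27 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.15e-13 with a preset correlation, adjusted p = 0.0466 with an estimated correlation). Without scramble-shRNA replicate E 1 member fell, as with no filter on low values. The laminin chain LAMA3, of the basement membrane, rose from 34.4 ± 2.14 to 126 ± 4.72 FPKM and LAMB3 from 112 ± 1.71 to 237 ± 7.08. THBS1, which encodes the matrix protein thrombospondin 1, rose from 25.2 ± 1.30 to 110 ± 1.91. In the other 9 splits of the 6 libraries into 3 and 3, in which 1 to 15 genes were called, camera called 2 to 11 lists with a preset correlation, against 12 here. With an estimated correlation it called 0 lists in these splits (0 or 1 at an unadjusted p under 0.05), against 3 here. Each of these splits has libraries of both labelled groups on each side. The difference between the labels therefore adds to their spread and can hold calls down. Part of it also stays in their contrast and can add calls, so these counts do not measure chance. The 3 calls with an estimated correlation, of the adhesion, TGF-beta and interferon lists, were lost with factors from the trimmed mean of M values (adjusted p = 0.0571), with quantile normalization (adjusted p of 0.0639 to 0.121) and with any 1 library left out (adjusted p of 0.0884 to 0.131). The TGF-beta and interferon correlations were estimated at -0.01 and -0.015, below the preset value, so correlation does not account for their larger p. A left-out library also removes degrees of freedom, so a call lost that way does not by itself show an unstable list.

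Mesenchymal markers and targets of TGF-beta also rose. Of 17 mesenchymal markers 10 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.45e-05, but adjusted p = 0.0543 with an estimated correlation). With no filter on low values 11 of 22 markers rose and 1 fell, with a list median of 0.26 on the log2 scale against 0.53, and without GPx1-shRNA replicate D 1 fell. Beside VIM and THBS1, TGFBI rose from 116 ± 3.54 to 200 ± 15.0 FPKM and COL6A1 from 1.76 ± 0.317 to 4.79 ± 0.158. Of 24 TGF-beta targets 12 rose and 1 fell, and 15 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.01e-06, adjusted p = 0.0466 with an estimated correlation). CCN2, the connective tissue growth factor, rose from 5.70 ± 0.399 to 25.05 ± 0.666, CCN1 from 17.8 ± 0.715 to 54.7 ± 0.472 and LTBP2 from 2.46 ± 0.0876 to 5.79 ± 0.356. The member that fell was ID1, from 407 ± 6.37 to 300 ± 22.4 FPKM, chosen after its values were seen, and 2 members fell with no filter on low values. The TGF-beta call with an estimated correlation was lost with no filter (adjusted p = 0.0548) and with any 1 library left out (adjusted p of 0.0884 to 0.131). YAP and TAZ targets rose in 8 of 22 members with 0 falls, also adjusted over the list alone (camera adjusted p = 1.45e-05, but adjusted p = 0.0729 with an estimated correlation). The receptor tyrosine kinase AXL rose from 15.99 ± 0.574 to 39.1 ± 1.52. CCN1, CCN2, THBS1 and TGFBI belong to more than 1 of these lists.

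Interferon response genes fell. Of 43 measured members 26 fell and 1 rose, and 27 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.26e-07, adjusted p = 0.0466 with an estimated correlation, but 0.0884 to 0.131 with any 1 library left out). UBE2L6, the conjugating enzyme of the ubiquitin-like protein ISG15, fell from 22.8 ± 1.00 to 2.17 ± 0.0556 FPKM. OAS3, which synthesises 2'-5'-linked oligoadenylates, fell from 18.7 ± 0.549 to 4.29 ± 0.156, and its relative OAS1 from 10.8 ± 2.24 to 1.57 ± 0.312. PARP14 fell from 11.8 ± 0.855 to 4.76 ± 0.216 and IFI27 from 13.2 ± 0.413 to 6.99 ± 0.222. The member that rose was TAP1, the peptide transporter of antigen presentation, from 26.9 ± 1.46 to 34.4 ± 1.87, chosen after its values were seen, and it lost its call without replicate D of either group. With a filter on a mean of 2 FPKM, 17 of 31 measured interferon genes fell. NF-kappaB and inflammatory genes rose in 6 and fell in 3 of 22 members, and 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.00823, but adjusted p = 0.135 with an estimated correlation). Without GPx1-shRNA replicate D or E, 3 of these genes rose. The chemokine CXCL8 rose from 3.84 ± 0.497 to 10.9 ± 0.347 and TNFAIP3 from 7.51 ± 0.496 to 14.6 ± 2.64, while TNFAIP2 fell from 51.8 ± 3.68 to 30.7 ± 3.28.

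**Figure D3:**
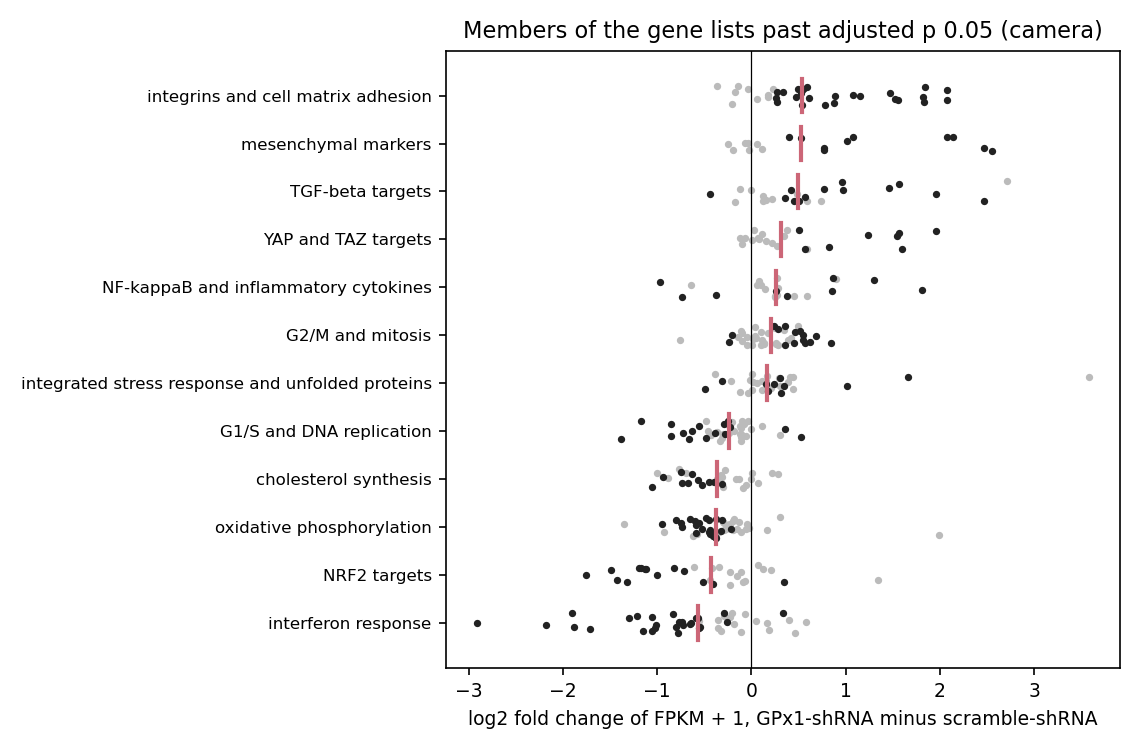
Log2 fold change of FPKM + 1 (GPx1-shRNA minus scramble-shRNA) of each measured member of the 12 gene lists called by camera with a preset correlation, with dark points for members past an adjusted p of 0.05, grey points for the others and a red bar at the list median. Medians run from -0.56 for the interferon response to 0.54 for integrins and cell-matrix adhesion.

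Genes of oxidative metabolism and lipid synthesis were lower. Of 49 nuclear oxidative phosphorylation genes 23 fell and 0 rose, and 31 fell adjusted over the list alone (camera adjusted p = 3.26e-07, but adjusted p = 0.356 with an estimated correlation). UQCRC2 of complex III fell from 58.6 ± 1.84 to 34.8 ± 0.680 FPKM and SDHD of complex II from 74.7 ± 2.81 to 47.2 ± 1.40. In cholesterol and fatty acid synthesis 11 of 29 members fell and 0 rose, and 12 fell adjusted over the list alone (camera adjusted p = 0.000808, but adjusted p = 0.113 with an estimated correlation). FASN, the fatty acid synthase, fell from 129 ± 2.64 to 66.7 ± 0.516 and FDFT1, the squalene synthase, from 71.1 ± 0.501 to 41.9 ± 2.22. Without scramble-shRNA replicate E 1 oxidative phosphorylation gene rose, and without scramble-shRNA replicate D or GPx1-shRNA replicate F 1 gene of cholesterol and fatty acid synthesis rose. Camera did not call glycolysis genes as a list (6 of 23 fell and 2 rose, 7 and 2 adjusted over the list alone, adjusted p = 0.0694). Fry called them lower (adjusted p = 0.000685). In that list the hexokinase HK2 fell from 19.98 ± 0.457 to 11.9 ± 0.541. Camera called this list, lower, with quantile normalization (adjusted p = 0.00479) and without GPx1-shRNA replicate E (adjusted p = 0.0406). With any 1 library left out other than GPx1-shRNA replicate D, 0 or 1 glycolysis genes rose.

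Targets of NRF2, the transcription factor of the oxidative stress response, fell in 13 of 28 members and rose in 1, and 14 fell and 1 rose adjusted over the list alone (camera adjusted p = 7.1e-05, but adjusted p = 0.222 with an estimated correlation). The malic enzyme ME1 fell from 17.6 ± 0.499 to 7.10 ± 0.265 FPKM, PIR from 12.03 ± 0.180 to 3.85 ± 0.106 and the aldo-keto reductase AKR1C3, whose close relatives share sequence, from 10.9 ± 0.972 to 2.52 ± 0.114. Of 19 selenoproteins 2 fell and 0 rose, also adjusted over the list alone, without a list call (camera adjusted p = 0.399). GPX2 fell from 15.2 ± 5.01 to 4.47 ± 0.190 and SEPHS2, which makes selenophosphate, from 43.2 ± 1.92 to 35.3 ± 1.32. SEPHS2 lost its call without scramble-shRNA replicate D or GPx1-shRNA replicate D or F (adjusted p of 0.0571 to 0.059). GPX4, the peroxidase of membrane lipids, was at 61.4 ± 5.43 and 47.8 ± 5.68 (adjusted p = 0.0685). Among 25 other antioxidant enzymes 3 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.399). PRDX4 rose from 27.9 ± 1.99 to 49.4 ± 1.89, and PRDX6 fell from 78.9 ± 4.72 to 55.6 ± 1.61. Without scramble-shRNA replicate D or E or GPx1-shRNA replicate E, 3 of these enzymes fell. Glutathione synthesis and conjugation had 2 rises and 4 falls among 22 members, also adjusted over the list alone (camera adjusted p = 0.599), with ANPEP higher (1.80 ± 0.162 to 5.86 ± 0.334) and GGT7 lower (4.83 ± 0.0953 to 2.27 ± 0.163). Ferroptosis regulators had 1 rise and 5 falls among 23, also adjusted over the list alone (camera adjusted p = 0.524). Without replicate D of either group, 2 glutathione genes and 3 ferroptosis regulators fell, and without scramble-shRNA replicate D, 1 glutathione gene and 0 ferroptosis regulators rose.

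Of 41 genes of G1/S and DNA replication 14 fell and 2 rose, and 15 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000617, but adjusted p = 0.135 with an estimated correlation). The replicative helicase subunit MCM2 fell from 53.9 ± 1.21 to 20.1 ± 0.714 FPKM and MCM6 from 37.0 ± 0.615 to 15.9 ± 1.18. Of 42 genes of G2/M and mitosis 13 rose and 2 fell, and 14 rose and 2 fell adjusted over the list alone (camera adjusted p = 3.92e-05, but adjusted p = 0.0637 with an estimated correlation). The cytokinesis kinesin KIF23 rose from 12.7 ± 0.296 to 23.6 ± 0.118 and PRC1, which bundles spindle microtubules, from 24.6 ± 0.187 to 36.5 ± 0.339. Without replicate D of either group 8 mitosis genes rose, and with any 1 library left out 0 or 1 fell. Without replicate D of either group, scramble-shRNA replicate E or GPx1-shRNA replicate F, 1 replication gene rose. The integrated stress and unfolded protein list rose in 8 and fell in 2 of 32 members, also adjusted over the list alone (camera adjusted p = 0.00278, but adjusted p = 0.142 with an estimated correlation). ASNS, the asparagine synthetase, rose from 3.95 ± 1.18 to 14.4 ± 1.96, and the chaperone HSP90B1 fell from 183 ± 8.82 to 147 ± 5.82, a call lost with quantile normalization (adjusted p = 0.0821). With any 1 library left out 3 to 6 members of this list rose, the fewest without replicate D of either group, and 1 or 2 fell.

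Camera made no list call for p53 targets (4 rose and 3 fell of 26), apoptosis regulators (1 rose and 8 fell of 32), hypoxia response (4 and 2 of 23) or metallothioneins and heat shock (3 and 3 of 19), each with the same counts adjusted over the list alone and camera adjusted p of 0.617, 0.399, 0.259 and 0.399. Fry called the apoptosis list lower (adjusted p = 0.00561). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 12.4 ± 1.15 to 21.0 ± 0.890 FPKM. The metallothionein MT1E, which has close paralogs, rose from 36.8 ± 2.07 to 80.5 ± 2.29, and CASP8 fell from 6.47 ± 0.329 to 4.47 ± 0.134. With any 1 library left out 3 to 5 apoptosis regulators fell, the fewest without scramble-shRNA replicate D or E, and 0 to 3 rose, the most without scramble-shRNA replicate D. Without scramble-shRNA replicate E or GPx1-shRNA replicate F, 1 p53 target and 1 hypoxia gene fell, and 1 hypoxia gene fell without replicate D of either group. Autophagy and lysosome genes had 3 rises and 11 falls among 44, and 3 and 12 adjusted over the list alone (camera adjusted p = 0.256). TFEB, a regulator of lysosomal genes, fell from 2.30 ± 0.304 to 0.522 ± 0.0699. Without scramble-shRNA replicate D 6 autophagy and lysosome genes fell, and 7 fell without scramble-shRNA replicate E, without GPx1-shRNA replicate D or with factors from the trimmed mean of M values. In this list 1 gene rose without replicate D of either group or GPx1-shRNA replicate E, and 5 rose with quantile normalization. PI3K and Akt genes had 5 rises and 3 falls among 32, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.256). Without GPx1-shRNA replicate E or F, 2 of these rose, and 3 rose with a filter on a mean of 2 FPKM. With any 1 library left out other than GPx1-shRNA replicate E, and with factors from the trimmed mean of M values, 1 fell. MAPK feedback and immediate early genes had 2 rises and 4 falls among 26, and 2 and 3 adjusted over the list alone (camera adjusted p = 0.536). Of these, KLF6 rose from 14.03 ± 0.598 to 33.4 ± 2.16. Without scramble-shRNA replicate E, 5 genes of this list rose, and without replicate F of either group 2 fell. Ribosomal proteins had 3 rises and 6 falls among 61, and 0 of either adjusted over the list alone (camera adjusted p = 0.0969). With any 1 library left out 0 or 1 of them rose and 2 to 8 fell, the fewest without scramble-shRNA replicate D or E or GPx1-shRNA replicate F and the most without GPx1-shRNA replicate E. With factors from the trimmed mean of M values 3 fell, and with quantile normalization 13. The ribosomal list was called, lower, with quantile normalization (adjusted p = 0.00712), without GPx1-shRNA replicate E (adjusted p = 0.00402) and without scramble-shRNA replicate F (adjusted p = 0.00194).

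Epithelial markers went both ways, with 5 rises and 6 falls among 31 members, also adjusted over the list alone (camera adjusted p = 0.876). Without scramble-shRNA replicate D or GPx1-shRNA replicate F, 3 fell. The keratins KRT7 (249 ± 10.8 to 402 ± 7.36 FPKM) and KRT18 (158 ± 5.22 to 222 ± 9.02) rose. The epithelial transcription factor ELF3 (9.35 ± 0.319 to 1.79 ± 0.0985) and the tight junction gene TJP3 (3.58 ± 0.452 to 0.557 ± 0.176) fell. CDH1, which encodes E-cadherin, and EPCAM were chosen after their values were seen. CDH1 was at 29.02 ± 0.745 in scramble and 27.8 ± 0.431 in GPx1-shRNA libraries (adjusted p = 0.413), and EPCAM at 111 ± 3.75 and 103 ± 0.504 (adjusted p = 0.159). Pancreatic markers had 2 rises and 4 falls among 7, also adjusted over the list alone (camera adjusted p = 0.386). In that list SOX9 rose from 7.70 ± 0.702 to 15.5 ± 1.17 and CEL fell from 10.9 ± 0.478 to 2.62 ± 0.144. Without scramble-shRNA replicate E or F, 1 pancreatic marker rose.

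Markers of other cell types were measured beside the mesenchymal genes. Of 5 fibroblast and stroma markers, MFAP5 (1.30 ± 0.182 to 3.37 ± 0.271 FPKM) and TAGLN rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.382, but fry adjusted p = 0.00561). The list's median log2 difference was -0.07 while its mean was 0.62. COL1A1, chosen after its values were seen, was at 0.916 ± 0.105 and 0.830 ± 0.0755 (adjusted p = 0.531). Of the blood and endothelial markers, CDH5 was at 0.502 ± 0.123 and 0.913 ± 0.234 (adjusted p = 0.0866, and 0.0473 without GPx1-shRNA replicate F) and CD68 at 17.3 ± 3.60 and 16.2 ± 3.79 (adjusted p = 0.786).

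Genes of gemcitabine uptake and metabolism had 1 rise and 5 falls among 20, also adjusted over the list alone (camera adjusted p = 0.399). The ectonucleotidase NT5E rose from 21.5 ± 1.17 to 64.7 ± 2.06 FPKM, and the drug exporters ABCG2 (5.08 ± 0.508 to 2.05 ± 0.335) and ABCC5 (12.9 ± 1.16 to 6.46 ± 0.366) fell. Without scramble-shRNA replicate D or GPx1-shRNA replicate F, 3 genes of this list fell. Genes beside GPX1 had 0 rises and 3 falls among 19, also adjusted over the list alone (camera adjusted p = 0.113). Those were IMPDH2 (91.7 ± 4.97 to 75.0 ± 1.67), KLHDC8B (3.55 ± 0.277 to 2.44 ± 0.318) and USP19 (6.18 ± 0.138 to 5.21 ± 0.106), and the last lost its call with factors from the trimmed mean of M values (adjusted p = 0.0711) and with each of the 6 libraries left out in turn. IMPDH2 lost its call without scramble-shRNA replicate D or GPx1-shRNA replicate D or F, and KLHDC8B without scramble-shRNA replicate E or F or GPx1-shRNA replicate D or F. Of 3 replication-dependent histone genes H2AC6 rose, from 2.64 ± 0.514 to 8.02 ± 0.0636.

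**Figure D4:**
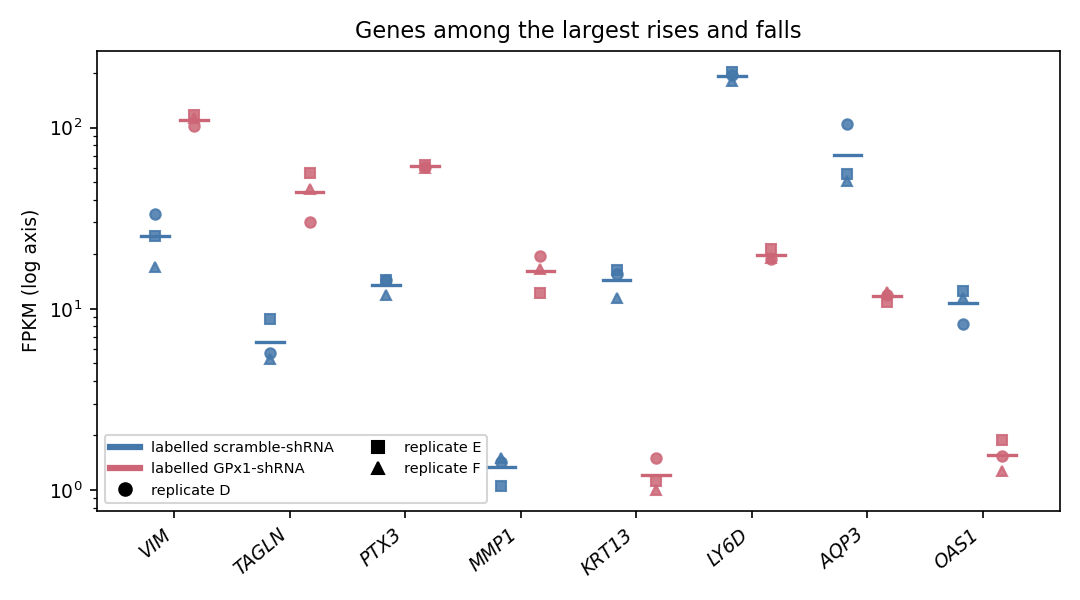
FPKM on a log axis of 8 genes among the largest rises and falls, with each library as a symbol, colours for the labelled groups and short lines at group means. The rule that named these genes required the 3 libraries of a group to lie apart from the 3 of the other. Examples are VIM, at 25.1 ± 8.12 and 110 ± 7.85 FPKM, and LY6D, at 193 ± 12.1 and 19.7 ± 1.36 FPKM.

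At the transcript level the same comparison gave 380 transcripts higher and 559 lower among 23501 tested (limma adjusted p under 0.05). Among the largest rises were a VIM transcript (ENST00000478746.1_2), which was near 0 in scramble libraries and at 26.8 ± 12.6 FPKM in GPx1-shRNA libraries, and a TAGLN transcript (ENST00000278968.10_2), from 0.334 ± 0.310 to 16.1 ± 10.8. The LAMA3 transcripts ENST00000587184.5_1 and ENST00000399516.7_2 were listed at 0 in the 3 scramble libraries and averaged 21.2 and 13.7 FPKM in the GPx1-shRNA libraries. Within a group, 195 transcripts were listed at 0 in a library and at 10 FPKM or more in another. An exact 0 of a transcript may therefore be a failed estimate. The largest falls past the threshold were in transcripts of IFITM1 (ENST00000328221.5_1, 33.5 ± 4.08 to 0.0123 ± 0.0213), CDCA4 (37.3 ± 2.82 to 2.21 ± 0.409), EEF1A2 (20.3 ± 7.95 to 0.940 ± 0.985), LY6D (364 ± 22.8 to 37.8 ± 2.45) and UBE2L6 (35.6 ± 3.31 to 2.99 ± 0.723). With any 1 library left out, 97 to 151 transcripts were higher and 142 to 177 lower. With the replicate letter as a block, 1 was higher and 1 lower. The TAGLN transcript lost its call without GPx1-shRNA replicate F or any single scramble library, with adjusted p of 0.0622 to 0.0765. The EEF1A2 transcript lost its call with each of the 6 libraries left out in turn (adjusted p of 0.0505 to 0.0879) and with a pseudocount of 0.1 FPKM (adjusted p = 0.0893).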

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

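The alternative without rows listed at 0, the list counts without scramble-shRNA replicate E, the runs with an estimated correlation under other settings and the counts of genes with transcripts called in both directions were chosen after seeing the data; the others were planned. Of the 24 genes with the largest rises and falls, 23 kept their call under each alternative computed, and ARL6IP5 lost it in 5 of the runs that left out a library. A 2-fold minimum left 127 genes higher and 206 lower, and 171 transcripts higher and 288 lower, because it adds a criterion. Camera with an estimated correlation called 3 lists and fry 21, against 12. Beyond these 12, fry called lower the lists of glycolysis, autophagy and lysosome, epithelial markers, apoptosis, ferroptosis, pancreatic markers and genes beside GPX1 (fry adjusted p of 0.000685 to 0.00976). It called higher those of PI3K and Akt (adjusted p = 0.0169) and of fibroblast and stroma markers (adjusted p = 0.00561). Fry does not compare a list with the other genes, and 26.3% of all genes tested were called, more of them lower. A fry call therefore does not show that a list changed more than other genes. Scaling moved the split of calls towards balance: 1333 genes higher and 1445 lower with factors from the trimmed mean of M values, 1350 and 1457 with quantile normalization. The share of calls that were higher was 38.3% in the main fit, 48% with these factors and 48.1% with quantile normalization. The excess of falls therefore depended largely on scaling. With rows at 0 left out, 1121 genes were higher and 1817 lower. Without scramble-shRNA replicate E, 22 integrin and adhesion genes rose and 27 interferon genes fell. Leaving out 1 library at a time gave 97 to 151 transcripts higher and 142 to 177 lower, with fewer samples in the fit.

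The GPX1 log2 fold change ranged from -0.376 to 2.227 over the runs that left out 1 library, negative without scramble-shRNA replicate E; its transcript ENST00000419783.1_1 ranged from -0.853, without that library, to 1.913. Near-0 differences also changed sign. MT-ND5 was at 0.051 with factors from the trimmed mean of M values and ranged from -0.027 to 0.008 with 1 library left out (0.007 without GPx1-shRNA replicate E). H4C5 was at 0.011 with quantile normalization and ranged from -0.194 to 0.006. H2BC5 ranged from -0.253 to 2.096 (-0.178 without GPx1-shRNA replicate F) and CD68 from -0.273 to 0.089. The camera direction of the epithelial markers turned, with list medians of -0.077 (filter on a mean of 2 FPKM), -0.062 (trimmed mean of M values), -0.061 (without GPx1-shRNA replicate E) and -0.102 (without GPx1-shRNA replicate F). Beyond the removed samples or rows, the cause was not tested. Of the named genes' other results, 2031 stayed on their side of the threshold, 46 lost a call and 2 gained one.

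Libraries of the same replicate letter showed no shared deviation: deviations from the group means correlated at -0.025, 0 and 0.026 for D, E and F. Whether libraries of a letter were prepared together cannot be told from these values. With the letter as a replicate block, 731 genes were higher and 1196 lower, and 1 transcript was higher and 1 lower, those of MT-ND2 and LY6D, so that the other named transcripts had no call and 0 genes had transcripts called in both directions, with fewer residual degrees of freedom. In that fit camera also called glycolysis (adjusted p = 0.0416) and ribosomal proteins (adjusted p = 0.00843), both lower, and with an estimated correlation the adhesion, TGF-beta and interferon lists were not called (adjusted p = 0.186 each). GPX4 had an adjusted p of 0.0349, and TNFAIP3 had 0.0514. No depth is known, so how far it limits low genes could not be stated. The planned count test was not run, since whole reads could not be recovered.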

Other observations

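The 3 gene lists of this paragraph were written after the largest changes had been seen and before their own members' values were seen, with none of the genes already named, and were adjusted over these 3 lists alone. Squamous and keratinocyte genes fell in 18 and rose in 4 of 45 members, and 21 fell and 7 rose adjusted over the list alone (camera adjusted p = 0.00852, adjusted p = 0.0475 with an estimated correlation). IVL, which encodes involucrin of the cornified envelope, fell from 13.7 ± 0.919 to 3.29 ± 0.512 FPKM (SD, n = 3 each) and KRT14 from 4.68 ± 0.849 to 0.956 ± 0.0779, while KRT17 rose from 155 ± 11.8 to 271 ± 22.8. The most abundant member, KRT6A, was at 662 ± 245 and 810 ± 277 (limma adjusted p = 0.629), and KRT5 at 240 ± 5.11 and 183 ± 27.0 (adjusted p = 0.0527). Some falls were in low genes, as for DSG3 (1.38 ± 0.180 to 0.190 ± 0.0215) and KRT16 (1.41 ± 0.231 to 0.387 ± 0.0985). Class I antigen presentation genes fell in 10 and rose in 1 of 17 members, and 11 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00195, adjusted p = 0.0386 with an estimated correlation). The transporter TAP1, which rose in the interferon list, was not a member of this list. HLA-B fell from 50.4 ± 1.601 to 20.2 ± 1.01 and PSME2, of the proteasome activator, from 39.1 ± 2.17 to 19.8 ± 0.441, while PDIA3 rose from 118 ± 2.48 to 154 ± 2.07; HLA genes share sequence, so their values are uncertain. Actin cytoskeleton genes rose in 19 and fell in 2 of 36 members, and 20 rose and 3 fell adjusted over the list alone (camera adjusted p = 5.8e-09, adjusted p = 0.0355 with an estimated correlation). FLNA, an actin cross-linker, rose from 268 ± 3.34 to 432 ± 3.01 and MYH9, a non-muscle myosin, from 109 ± 2.42 to 195 ± 2.78, while PDLIM1 fell from 62.4 ± 3.87 to 45.6 ± 1.69. Each list kept its direction and, with a preset correlation, an adjusted p of at most 0.0131 with factors from the trimmed mean of M values, with quantile normalization and with each library left out, runs chosen after seeing the data. With an estimated correlation the 3 calls were lost with 1 library left out (adjusted p of 0.0538 to 0.109), except that of the actin list without GPx1-shRNA replicate F (adjusted p = 0.0438). Those fits have fewer residual degrees of freedom. In these runs 2 squamous genes rose without scramble-shRNA replicate F and 6 with quantile normalization, and 2 class I genes rose with either scaling. The shared change in each group is therefore a hypothesis, found and tested on the same libraries.

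In 9 genes, transcripts were called in both directions, among 837 genes with a called transcript. These genes were chosen after their values were seen. The SNRPN transcript ENST00000390687.8_1 rose from 5.36 ± 0.864 to 27.5 ± 2.14 FPKM while ENST00000577565.1_1 fell from 16.8 ± 1.58 to 1.69 ± 1.46. For EIF4B, a translation initiation factor, ENST00000262056.13_1 rose from 29.3 ± 9.30 to 89.8 ± 4.08 while ENST00000420463.7_1 fell from 107 ± 13.4 to 22.4 ± 4.49. For PLOD2, a lysyl hydroxylase of collagen, ENST00000494950.5_1 rose from 1.43 ± 0.122 to 16.4 ± 2.73 while ENST00000282903.9_1 fell from 13.7 ± 1.58 to 6.49 ± 0.562. In runs chosen after seeing the data, 4 to 11 genes had calls in both directions with 1 library left out, of which 1 to 3 were among the 9. SNRPN was not among them without scramble-shRNA replicate D or E, EIF4B was among them without scramble-shRNA replicate F alone, and PLOD2 without scramble-shRNA replicate E alone.

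MiaPaCa-2 is generally described as a poorly differentiated line with low E-cadherin. In each of these 6 libraries CDH1 lay at or above the 89.1 percentile of listed genes and EPCAM at or above the 98.2 percentile, both chosen after their values were seen. VIM lay between the 81.5 and 91.1 percentile in the scramble libraries. No reference profile of the line was used here, so the identity of the cells rests on the labels.

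Of the tests that follow, those of an exchanged library, fibroblasts, scaling and other splits of the samples were chosen only after the result was seen. GPX1 was not lower in the libraries labelled GPx1-shRNA. Each library, left out of the fit in turn, lay nearer its own group at 89.5% to 92.1% of the genes called from the other 5. The bound set beforehand was over 90% in each library; scramble-shRNA replicate E missed it at 89.5%, so a mislabelled library stays open by that test. An exchange of 1 or 2 libraries between the groups is argued against, since each library's mean correlation with its own group exceeded that with the other group by at least 0.0227 over 11941 listed genes and 0.0265 over the 11041 tested; an exchange of all 3 would leave these margins as they are and stays open. The within-group SD of GPX1 was above that of 99.5% of 3624 genes with a mean of 10 FPKM or more. GPX1 ranged from 1.21 to 80.6 FPKM among the scramble libraries, which by their labels carry a control hairpin. A hairpin that left GPX1 RNA in place therefore cannot account for the spread in that group. An unstable FPKM estimate cannot be told from other sources of the spread. Whether GPX1 RNA was left in place in the GPx1-shRNA libraries cannot be decided, since a spread this wide could hide a fall.

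Mesenchymal, TGF-beta and adhesion lists were higher by camera with a preset correlation, while with an estimated correlation the mesenchymal list had an adjusted p of 0.0543 and the others 0.0466. Fibroblast RNA in the GPx1-shRNA libraries is argued against: the COL1A1 log2 difference was -0.066, and COL1A1 and COL1A2 averaged 0.830 and 0.0299 FPKM there beside VIM at 110. Fry did call the fibroblast and stroma list higher (adjusted p = 0.00561), with TAGLN and MFAP5 as the members that rose. Scaling was examined with factors from the trimmed mean of M values, under which the largest camera adjusted p with a preset correlation was 2.64e-05. A scale factor shifts the genes of a library nearly alike, and camera compares a list with the other genes. That p could hardly change, so nothing on scaling is concluded from it. The list medians were 0.586, 0.521 and 0.595 with these factors (SD over members 0.968, 0.812 and 0.700). In the main fit they were 0.531, 0.494 and 0.540 (SD 0.964, 0.809 and 0.699). The mesenchymal median was 0.256 with no filter on low values. These factors moved the median over all genes from -0.049 to -0.004, too little to account for the list medians. With an estimated correlation these factors took the TGF-beta p from 0.00466 to 0.00571 and the adhesion p from 0.00415 to 0.00511, which ended both calls after adjustment (adjusted p = 0.0571). The hairpin and a difference between the cell populations that carry each construct stay open and cannot be separated with 1 construct per group.

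The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split, which was the 1 split with as many calls, gave 2909 genes, 939 transcripts and 12 gene lists. The highest of the other splits gave 15 genes, 16 transcripts and 11 lists. Each of these mixes libraries of both labelled groups on each side. That widens their spread and can hold calls down, while part of the difference between the labels stays in their contrast and can add calls. Their counts therefore do not measure chance.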
